A study of Homo sapiens with 6 samples.

How the data were processed

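Polyadenylated RNA was sequenced from 6 libraries of H2170, an established cell line of human lung squamous cell carcinoma. The cells expressed GFP alone (Control), wild-type ACK1 fused to GFP (WT) or ACK1 carrying the change called IDRmut, also fused to GFP (IDRmut), with 2 libraries per group. ACK1 is a non-receptor tyrosine kinase encoded by TNK2. The labels do not spell out IDRmut or list the altered residues. IDR is the usual abbreviation of intrinsically disordered region, the kind of flexible protein segment through which many proteins form condensates, and it is read here in that sense. Per the labels' protocols, RNA was isolated with Trizol, mRNA was captured on poly-T beads, cDNA was primed with random hexamers, and the libraries were amplified by PCR and sequenced as DNA nanoballs.

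The deposited table held raw counts per gene for every library, not normalized by the authors. Per the submitters' processing notes, the tools were HISAT2 2.2.1, SAMtools 1.14 and featureCounts 2.0.1 with the genome build GRCh38. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads of a gene and of a gene overlapping it on either strand therefore could not be separated, and the share of exon bases overlapped is given for named genes where it was large. Families with near-identical members, such as the histones, HLA genes and interferon-induced gene clusters, carry the same uncertainty. Reads from the ACK1 transgene and from endogenous TNK2 could not be separated either, and GFP had no entry among the genes used.

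The table listed 61487 gene IDs. Current names were matched to 61367 of them, names from GENCODE release 29 to 107 more, and 13 stayed without a name. Coordinates and exon overlaps came from GENCODE release 29 on GRCh38, which held positions for 16299 of the genes tested; this release may not be the authors'. Library totals were 20154935 and 19128111 counts in Control, 20033289 and 33540998 in WT, and 20346572 and 21922477 in IDRmut. The second WT library was the deepest, so its values carry the smallest counting error. PCR reads without molecular identifiers are not independent molecules, so intervals and floors from counts cover counting error only.

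Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 16591 genes holding between 99.8% and 99.9% of each library's counts. Libraries were scaled with TMM. All 6 libraries entered a single fit of group means with edgeR 4.0.16 in R 4.3.3, because 2 libraries per group leave few degrees of freedom, and the 3 contrasts were tested with edgeR's quasi-likelihood test. Values of p were adjusted by the Benjamini-Hochberg method over the 16591 genes, and a gene was called at an adjusted p under 0.05. The biological coefficient of variation was 0.0294, with 3 residual and 13.5 prior degrees of freedom. Levels are CPM, counts divided by the TMM-scaled library size, given as mean ± SD with n = 2. Log2 fold changes are given ± SE. Where a group had no count over both libraries, the fold was computed against a floor of 3 counts over that group, and with 1 to 3 counts a ratio with a 95% counting interval was given in place of the fitted fold.

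Before the data were examined, 39 gene lists were written from general knowledge, of which 6 hold markers of other cell types, and the alternatives and the rule for naming genes were fixed. A list was tested when at least 5 members passed the filter, which 34 did. The test was limma's camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 34 lists. It was repeated with an estimated correlation and with fry. With an estimated correlation, camera takes only the 3 residual degrees of freedom, so its adjusted p are larger for that reason as well. A list that does not pass that way is not shown to be unchanged. The named genes are TNK2, STAT5A and STAT5B; per contrast the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM and replicates that did not overlap; up to 3 members per list with the smallest adjusted p; and any member of the STAT5 target list. Genes named outside this rule are marked as chosen after their values were seen. A few genes that meet the rule are not reported here.

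The procedure was tested on simulated counts drawn from the real means and library sizes. In the simulated comparison of WT with Control, run over 16591 genes, 44 of 67 genes changed 1.5-fold were called, 50 of 67 changed 2-fold and 65 of 66 changed 4-fold. In the same run 17 of 16361 unchanged genes were called, 8.54% of all 199 calls; the remaining calls include 23 of 30 genes shifted 1.3-fold as a list to test camera. A simulated comparison of IDRmut with Control in which nothing was changed gave 3 calls among 16591 genes. Overlaps between contrasts that share libraries were set beside 20 simulations without effects.

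Alternatives were RLE and upper-quartile scaling, the DESeq2 1.42.0 Wald test, limma-voom, no or a stricter low-count filter, a replicate block, fits of only the groups compared, stricter thresholds, and leaving out each library. Added after the data were seen were an offset for the trend of each library with GC content and transcript length, and counts without genes of shifted segments of chromosomes 1 and 7. With 2 libraries per group, tests that need larger groups, such as other splits of the samples or a search for outlying libraries, were not possible.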

Results

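Gene expression was compared between H2170 lung squamous carcinoma cells expressing GFP, wild-type ACK1-GFP and IDRmut ACK1-GFP, in a series whose stated subject is gene regulation through ACK1 condensates and STAT5; condensates were not measured in these libraries. Each group had 2 libraries, with 20154935 and 19128111 counts in Control, 20033289 and 33540998 in WT and 20346572 and 21922477 in IDRmut. Replicates ranked genes alike, with Spearman correlations across genes of 0.996 in Control, 0.997 in WT and 0.996 in IDRmut. The leading principal component held 62.4% of the variance and separated Control from both ACK1 arms, and the next held 19.5% and separated WT from IDRmut. Replicate counts differed by more than counting error, with a chi-square per gene of 1.70 in Control, 1.53 in WT and 3.72 in IDRmut, so each library was counted as a sample. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

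TNK2, the gene of ACK1, was expressed far above Control in both arms and was higher in WT than in IDRmut. It lies on chromosome 3 from 195863364 to 195911945 (GRCh38, minus strand; ENSG00000061938), and its level was 42.1 ± 1.41 CPM in Control, 3564 ± 69.8 CPM in WT and 1609 ± 217 CPM in IDRmut (SD, n = 2). The fitted ratios were 84.6 for WT over Control, 38.2 for IDRmut over Control and 2.22 for WT over IDRmut. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, these log2 fold changes of 6.40 ± 0.08, 5.25 ± 0.08 and 1.15 ± 0.06 had adjusted p of 1.1e-18, 1.8e-17 and 2.8e-10. TNK2 took 0.358% and 0.368% of all counts in WT and 0.176% and 0.146% in IDRmut. The antisense gene TNK2-AS1, which overlaps 2.45% of the TNK2 exon bases, had between 4 and 20 counts per library. Every difference between WT and IDRmut below was therefore measured together with this difference in ACK1 transcript level.

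**Figure D1:**
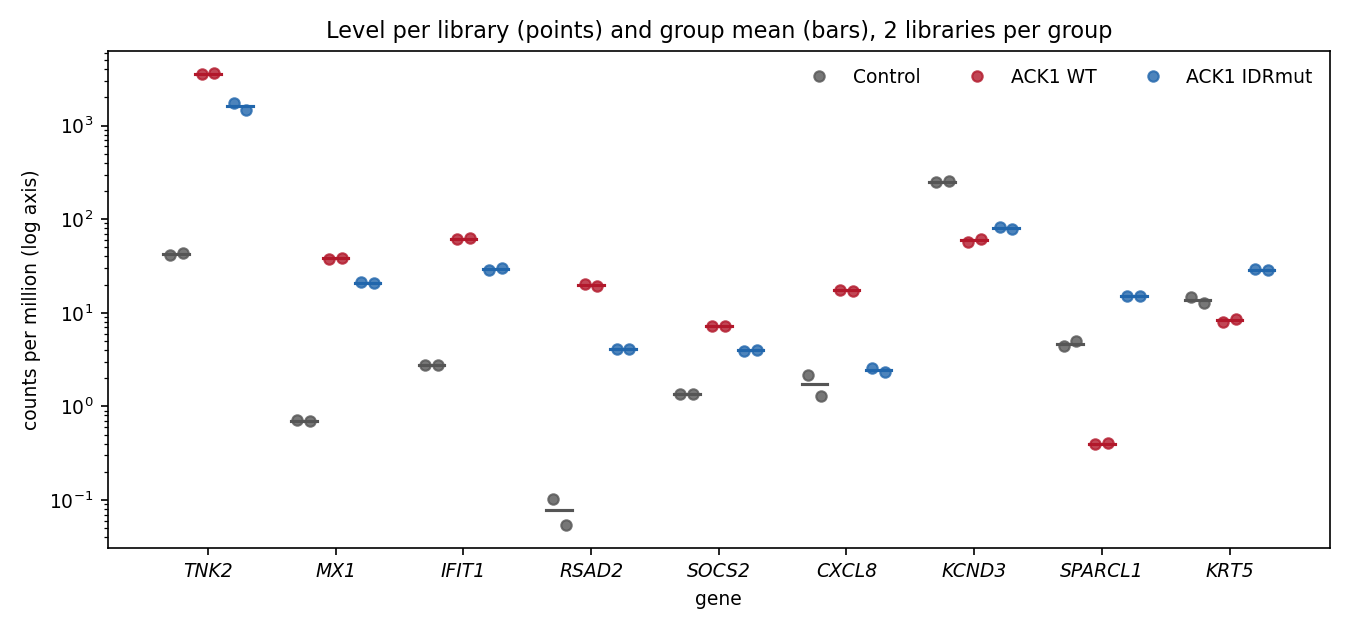
Level of 9 named genes in each of the 6 libraries, in CPM on a log axis; points are libraries and bars are group means. TNK2 lies near 42.1 CPM in Control, 3564 CPM in WT and 1609 CPM in IDRmut, and the interferon-induced genes MX1, IFIT1 and RSAD2 follow the same order, while SPARCL1 and KRT5 are lowest in WT and highest in IDRmut.

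Interferon-induced genes showed the broadest rise in WT compared with Control. Of 50 measured members of the interferon response list, 45 rose and 2 fell (46 and 2 adjusted over the list alone), with a median log2 fold change of 1.69. IFIT1, which binds viral RNA, rose from 2.79 ± 0.0048 to 62.1 ± 0.48 CPM, and MX1, an antiviral GTPase on chromosome 21 (41420304 to 41459214), rose from 0.705 ± 0.0078 to 38.1 ± 0.68 CPM (SD, n = 2). IFI6 rose by 2.65 ± 0.07 on the log2 scale. Camera gave the list an adjusted p of 1.2e-104, against an adjusted p = 0.097 with an estimated correlation. Antigen presentation genes rose with them: 13 of 17 members rose and none fell (13 and 0 adjusted over the list alone), led by HLA-B (1.60 ± 0.04; 18.9% of its exon bases overlapped), HLA-C (0.76 ± 0.04) and the peptide transporter TAP1 (0.76 ± 0.06). Its camera adjusted p was 5.0e-12, and the adjusted p = 0.13 with an estimated correlation; 3 of the listed genes stand on the interferon list too.

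Targets of TGF-beta signalling and genes of the epithelial-mesenchymal transition were also higher in WT than in Control. Of 21 measured TGF-beta targets, 16 rose and 4 fell (16 and 4 adjusted over the list alone), and of 32 transition genes 18 rose and 6 fell (19 and 7 adjusted over the list alone). TGFBI, an extracellular matrix protein, rose by 1.59 ± 0.04 and ID3, an inhibitor of helix-loop-helix transcription factors, by 0.76 on the log2 scale. Camera adjusted p were 1.8e-10 and 1.8e-08, and with an estimated correlation adjusted p = 0.14 for both lists. Inflammatory genes rose in 11 of 20 cases and fell in 2 (13 and 2 adjusted over the list alone), among them CXCL8, a neutrophil chemoattractant, from 1.74 ± 0.63 to 17.4 ± 0.39 CPM (SD, n = 2); the camera adjusted p was 8.9e-05, and the adjusted p = 0.13 with an estimated correlation. Of 13 measured replication-dependent histone genes, whose transcripts mostly lack poly-A tails, 9 rose and none fell (9 and 0 adjusted over the list alone). That list had a median of 0.98 and a camera adjusted p of 0.0014, with adjusted p = 0.14 with an estimated correlation.

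Lower in WT were genes of DNA replication, squamous epithelium and MAPK feedback. Replication genes fell in 37 of 51 cases and rose in 2 (41 and 3 adjusted over the list alone), with a median of -0.24 and with POLA1, the catalytic subunit of DNA polymerase alpha, at -0.46 ± 0.04. MAPK output and feedback genes fell in 13 of 22 cases and rose in 3 (13 and 3 adjusted over the list alone), including DUSP4, a phosphatase of MAP kinases, at -0.92 ± 0.04 and SPRY4 at -0.82 ± 0.04. Squamous and basal epithelial genes fell in 16 of 28 cases and rose in 10 (17 and 10 adjusted over the list alone); S100A2 fell by 1.20 and the basal keratin KRT14 by 1.20 on the log2 scale. Camera adjusted p for these lists were 4.4e-08, 3.1e-09 and 2.5e-06, and with an estimated correlation adjusted p = 0.099, 0.13 and 0.16.

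Among single genes, SULF1, a heparan sulfate endosulfatase on chromosome 8 (69466624 to 69660915), had no count in either Control library and 19.7 ± 0.56 CPM in WT (SD, n = 2), at least 253-fold higher against a floor of 3 counts over the Control group. It was among 36 genes with at most 3 counts over both Control libraries and at least 40 in each ACK1 arm after all libraries were thinned to 19128111 counts. RSAD2, the antiviral protein viperin (chromosome 2, 6865806 to 6898239), had 3 counts in Control and a WT to Control ratio of 250 (95% counting interval 85.4 to 1215). Among called genes with a mean of at least 5 CPM, the largest other rises were those of NLRP1, IFI44L, MX1, IFI27, OAS1, IFIT2 and FKBP10, with log2 fold changes between 5.07 and 6.32 beside the 6.40 of TNK2. The largest falls were those of MAF (-3.53 ± 0.15), SPARCL1 (-3.52 ± 0.22), the imprinted noncoding RNA H19 (-3.15 ± 0.11), NOS2 (-2.58 ± 0.10) and CDH5 (-2.43 ± 0.04). PADI3, FBLN2, EDNRA, the potassium channel gene KCND3 and CES1 followed, from -2.27 to -2.01. CDH5, known as an endothelial cadherin, stood at 213 ± 3.8 CPM in Control and 39.4 ± 0.30 CPM in WT and made up most of the sum of the endothelial markers.

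In all, edgeR's quasi-likelihood test called 5807 of 16591 genes between WT and Control, 2889 higher and 2918 lower. The share of calls that were higher, 49.8%, was 58.6% of 5741 with upper-quartile scaling and 40.7% of 7076 with a correction for GC content and transcript length chosen after the data were seen. The called genes changed by a factor of 2 or more in 846 cases upward and 210 downward. Camera called 12 of 34 lists higher and 5 lower, and none held with an estimated correlation, which leaves camera 3 degrees of freedom and little power. DESeq2 called 3649 genes, each of them also called by edgeR in the same direction.

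Interferon genes rose in IDRmut cells too, and replication genes were lower than in Control. In the interferon list 44 of 50 members rose and none fell (44 and 0 adjusted over the list alone), with a median log2 fold change of 1.26, or 1.18 with genes without Control counts set at their bound; MX1 reached 21.1 ± 0.64 CPM and IFIT1 29.3 ± 1.28 CPM (SD, n = 2). Antigen presentation genes rose in 13 of 17 cases and fell in none (15 and 0 adjusted over the list alone), with HLA-B at 2.05 ± 0.04 and HLA-F, with 34.4% of its exon bases overlapped by other genes, at 1.67 on the log2 scale. Replication genes fell in 47 of 51 cases and rose in none (48 and 1 adjusted over the list alone), with a median of -0.28, and mitotic genes fell in 31 of 47 and rose in 1 (34 and 2 adjusted over the list alone). MKI67, the proliferation antigen, stood at 1205 ± 23 CPM in Control and 859 ± 22.8 CPM in IDRmut (SD, n = 2), and RRM2, a subunit of ribonucleotide reductase with 20.2% of its exon bases overlapped, changed by -0.49.

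Camera adjusted p in IDRmut against Control were 1.5e-63 for the interferon list and 1.7e-20 for replication, and both held with an estimated correlation, at adjusted p of 0.0090 and 0.023. Antigen presentation (5.2e-20 by camera) had an adjusted p = 0.051 with an estimated correlation, and mitotic genes (9.4e-11) an adjusted p = 0.12 with an estimated correlation. MAPK feedback genes fell in 13 of 22 cases and rose in 2 (15 and 2 adjusted over the list alone), DUSP4 by 1.10, at a camera adjusted p of 7.9e-14, with adjusted p = 0.058 with an estimated correlation. Cytosolic ribosomal protein genes rose in 35 of 77 cases and fell in none (36 and 0 adjusted over the list alone), by a median of 0.10, at a camera adjusted p of 1.5e-04 and adjusted p = 0.31 with an estimated correlation. Squamous genes went both ways in IDRmut, with 11 higher and 10 lower of 28 (11 and 10 adjusted over the list alone) and a camera adjusted p of 0.90; KRT6A rose by 1.76 ± 0.06 and S100A2 fell by 1.03.

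SULF1 was at least 259-fold higher in IDRmut than in Control, and the chemokine CXCL14 (chromosome 5, 135570679 to 135579279) rose from 0.526 ± 0.17 to 72.0 ± 3.6 CPM (SD, n = 2). NLRP1, IFI44L, FKBP10, MX1, OAS1 and IFI27 had log2 fold changes between 4.08 and 6.66, and the ratio for RSAD2 was 52.8 (95% counting interval 17.8 to 258). MAF (-3.12 ± 0.15), H19 (-2.85 ± 0.11) and DAB1 (-2.27 ± 0.12) fell most, ahead of NOS2, ARAP2, CES1, PTGES, PADI3, KCND3 and BRME1, which lay between -1.98 and -1.45. The quasi-likelihood test of edgeR called 5237 genes, 2591 higher and 2646 lower, of which 718 and 144 changed by a factor of 2 or more. With upper-quartile scaling 58.1% of 5283 calls were higher, against 49.5%. Camera called 7 lists higher and 3 lower, of which 2 held with an estimated correlation. DESeq2 called 3290 genes, all among those of edgeR, and without Control replicate 1 edgeR called 3451.

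Interferon, mitotic, TGF-beta, squamous and glycolytic genes stood apart between WT and IDRmut by camera with the preset correlation, and no list did with an estimated correlation (smallest adjusted p = 0.12). Interferon genes were higher in WT in 33 of 50 cases and lower in 2 (35 and 3 adjusted over the list alone), with a median log2 fold change of 0.45; RSAD2 differed by 2.25 ± 0.10 and IFIT2 by 1.94 ± 0.09. Mitotic genes were higher in WT in 39 of 47 cases and lower in 1 (40 and 1 adjusted over the list alone), with the mitotic transcription factor FOXM1 at 0.54 ± 0.04. Against Control, 14 mitotic genes rose and 6 fell in WT (17 and 8 adjusted over the list alone), with a median of 0.03 and a camera adjusted p of 0.47, while 31 fell in IDRmut. Replication genes were higher in WT than in IDRmut in 23 of 51 cases and lower in 1 (24 and 1 adjusted over the list alone). TGF-beta targets were higher in 13 of 21 cases and lower in 1 (14 and 1 adjusted over the list alone) and the differences of ID2 and ID3, inhibitors of helix-loop-helix transcription factors, were 0.92 and 0.81. Squamous genes were lower in WT in 18 of 28 cases and higher in 8 (19 and 9 adjusted over the list alone), with the basal keratin KRT5 at -1.79 ± 0.09 and KRT6A at -1.10 ± 0.05. Glycolysis and hypoxia genes were lower in 17 of 36 and higher in 1 (18 and 1 adjusted over the list alone), led by NDRG1 (-0.98), CA9 (-2.07) and hexokinase HK2 (-0.82); 38.5% of the CA9 exon bases overlap another gene.

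Camera adjusted p between WT and IDRmut were 6.1e-22 for interferon, 2.2e-18 for mitotic, 1.4e-19 for TGF-beta and 3.6e-11 for glycolysis and hypoxia genes, each with adjusted p = 0.12 with an estimated correlation. Squamous genes had 2.2e-11 and replication genes 9.0e-04 by camera, both with adjusted p = 0.14 with an estimated correlation. Mitochondrially encoded transcripts were lower in WT in 10 of 15 cases and higher in none (11 and 0 adjusted over the list alone), at a camera adjusted p of 3.0e-09 and adjusted p = 0.27 with an estimated correlation. Ribosomal protein genes were lower in 29 of 77 and higher in none (31 and 0 adjusted over the list alone), by a median of -0.07, at 3.3e-04 by camera and adjusted p = 0.23 with an estimated correlation. YAP-TEAD targets were higher in 14 of 24 and lower in 2 (14 and 2 adjusted over the list alone), with the receptor kinase AXL at 0.88 ± 0.04 and a camera adjusted p of 4.9e-08, against adjusted p = 0.14 with an estimated correlation.

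CXCL8 (chromosome 4, 73740506 to 73743716) had the largest rise in WT over IDRmut among called genes with a mean of at least 5 CPM, 2.83 ± 0.14 on the log2 scale, and RSAD2, GPRC5A, IFIT2, PCDH1, IFIT3, GATA2 and PTGES, from 2.25 to 1.51, and MISP were also among the largest rises. SPARCL1, a matricellular protein on chromosome 4 (87473335 to 87531061), was lower in WT by -5.22 ± 0.17, with 0.401 ± 0.012 CPM in WT and 15.2 ± 0.054 CPM in IDRmut (SD, n = 2), and Control between them at 4.68 ± 0.38 CPM. CXCL14 (-2.53 ± 0.07), FAT2, PI15, CA9, TXNIP, SYT12, ABI3BP, BGN and KRT5 followed, down to -1.79. By edgeR's quasi-likelihood test 4396 genes differed, 2350 higher and 2046 lower in WT, with 219 and 205 of them by a factor of 2 or more; camera called 15 lists higher and 6 lower, and 0 held with an estimated correlation. DESeq2 called 2435 genes, all among those of edgeR, and without ACK1 WT replicate 2 edgeR called 2590. After a correction for GC content and transcript length chosen after the data were seen, 42.2% of 5722 calls were higher in WT, against 53.5% without it.

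**Figure D2:**
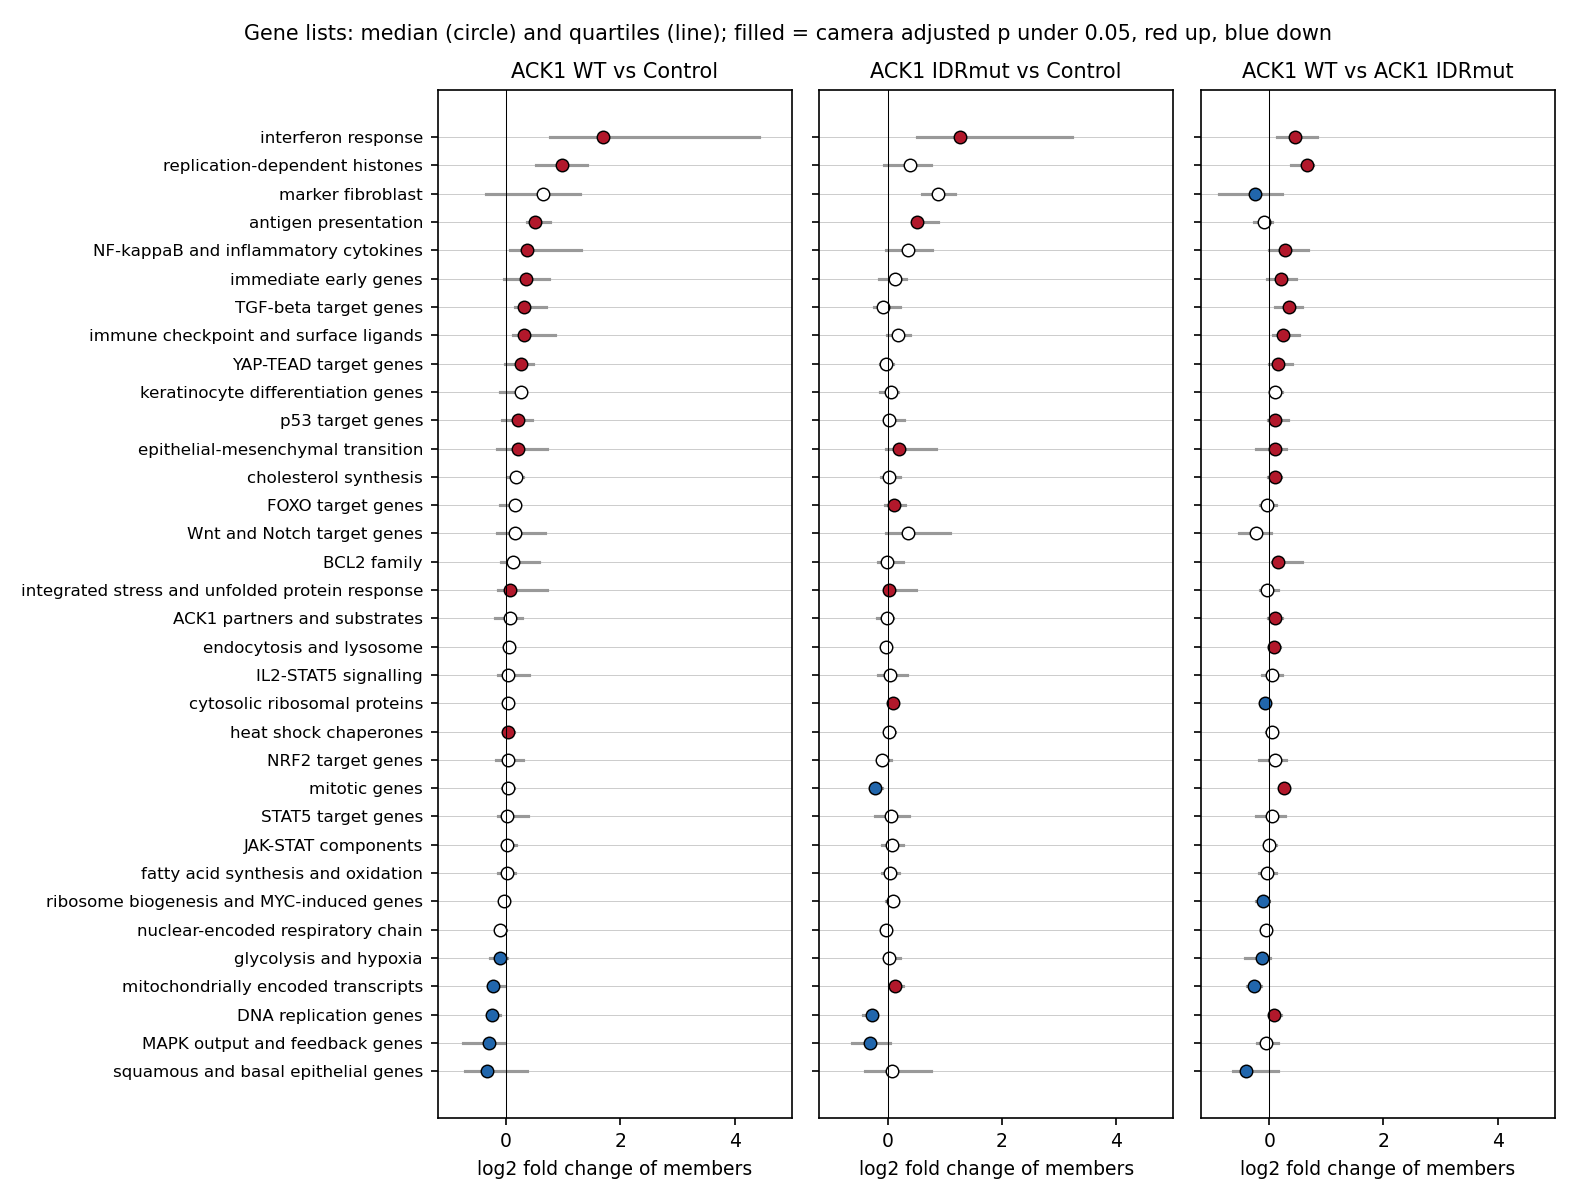
Median log2 fold change (circles) and quartiles (lines) of the members of 34 gene lists in the 3 comparisons; filled circles had a camera adjusted p under 0.05 with the preset correlation, red for higher and blue for lower. The interferon list has medians of 1.69, 1.26 and 0.45, and the STAT5 target list lies at 0.01, 0.05 and 0.06.

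STAT5 targets passed camera and the directional fry test in none of the 3 comparisons, and members went both ways. Of 23 measured members, 6 rose and 5 fell in WT against Control (6 and 5 adjusted over the list alone), 7 rose and 8 fell in IDRmut against Control (8 and 9 adjusted over the list alone), and 7 were higher and 5 lower in WT than in IDRmut (8 and 5 adjusted over the list alone). Camera adjusted p were 0.31, 0.58 and 0.55, and those of fry, which tests for a common direction without comparing with other genes, were 0.063, 0.22 and 0.27. SOCS2, an inhibitor of cytokine receptor signalling on chromosome 12 (93569814 to 93583487), rose from 1.36 ± 0.018 CPM in Control to 7.20 ± 0.072 CPM in WT and 3.99 ± 0.085 CPM in IDRmut (SD, n = 2), and its WT to IDRmut difference of 0.85 ± 0.13 had an adjusted p of 7.5e-05 by edgeR's quasi-likelihood test. CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 1.20 ± 0.06 in WT and 0.59 ± 0.06 in IDRmut, and EGR1 by 0.80 ± 0.06 and 0.32 ± 0.07. FOS fell in both arms, at -1.09 ± 0.10 in WT and -0.46 ± 0.10 in IDRmut, as did MCL1 at -0.23 and -0.17. MYC rose by 0.51 ± 0.05 in IDRmut, with an edgeR adjusted p of 2.4e-07, and had -0.09 ± 0.05 in WT (adjusted p 0.17 by edgeR), where it was called lower with the correction for GC content and length (edgeR adjusted p 0.0026) and without ACK1 IDRmut replicate 1 (0.047). ID1 rose in WT by 0.31 ± 0.05 and fell in IDRmut by 0.24 on the log2 scale.

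Several members moved in one arm or by smaller amounts. IRF1, with 28.0% of its exon bases overlapped, rose by 0.44 ± 0.07 in WT and 0.57 ± 0.07 in IDRmut, and DUSP5 fell in both arms, at -0.33 ± 0.07 in each. Among those called against Control in IDRmut and not in WT were rises of CCND3 (0.34 ± 0.05) and PRLR (0.30 ± 0.07) and falls of BCL2 (-0.49 ± 0.11), CDK6 (-0.30 ± 0.04) and BCL2L1 (-0.19 ± 0.04), besides MYC; 43.0% of the BCL2L1 exon bases overlap another gene. Called in WT and not in IDRmut were falls of BCL6 (-0.34 ± 0.06) and SPRED2 (-0.20 ± 0.05), besides the rise of SOCS1. The difference between the arms itself was not called for SPRED2 and SOCS1 (edgeR adjusted p 0.34 and 0.068), though that of SOCS1 passed without ACK1 IDRmut replicate 1 (0.044). It was called for BCL2 (0.35 ± 0.11, edgeR adjusted p 0.024) but lost with DESeq2 (adjusted p 0.22), without ACK1 WT replicate 2 (edgeR adjusted p 0.21) and without ACK1 IDRmut replicate 2 (0.17). The SPRED2 call in WT was lost with DESeq2 (adjusted p 0.058), without Control replicate 2 (edgeR adjusted p 0.092) and without ACK1 WT replicate 2 (0.14), and with the correction for GC content and length SPRED2 passed in IDRmut (0.021). Those of PRLR and BCL2L1 in IDRmut were lost without Control replicate 2 (edgeR adjusted p 0.056 and 0.059). CDK6 was called lower in WT too with the correction for GC content and length (edgeR adjusted p 0.018), in the fit of only the groups compared (0.049), and without ACK1 IDRmut replicate 1 (0.025) or 2 (0.035). CISH, a feedback inhibitor of STAT5, had 14 counts in Control, 32 in WT and 33 in IDRmut, and fold changes of 0.68 ± 0.42 in WT and 1.08 ± 0.41 in IDRmut with edgeR adjusted p of 0.24 and 0.055; the latter passed with upper-quartile scaling (edgeR adjusted p 0.049) and with the correction for GC content and length (0.046). SOCS1 rose by 1.29 ± 0.38 in WT (edgeR adjusted p 0.013), a call lost with DESeq2 (adjusted p 0.15), without Control replicate 1 (edgeR adjusted p 0.19) and without ACK1 WT replicate 2 (edgeR adjusted p 0.10), and had 0.41 ± 0.45 in IDRmut. PIM1 had 0.04 in WT and -0.05 in IDRmut, and BCL2L1 had 0.01 in WT. Of the STAT5 transcripts, STAT5A had 0.41 ± 0.13 in WT (edgeR adjusted p 0.022) and 0.20 ± 0.14 in IDRmut (edgeR adjusted p 0.31), and its call in WT was lost with DESeq2 (adjusted p 0.17), without Control replicate 2 (edgeR adjusted p 0.23) and without ACK1 WT replicate 1 (edgeR adjusted p 0.099). STAT5B had 0.08 ± 0.06 and 0.15 ± 0.06, with edgeR adjusted p of 0.32 and 0.058. In IDRmut it passed with upper-quartile scaling (edgeR adjusted p 0.024), the stricter filter (0.040), the correction for GC content and length (0.020) and without ACK1 IDRmut replicate 1 (0.019). RNA levels do not measure STAT5 phosphorylation.

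Wider lists around ACK1 and STAT5 did not pass camera, which compares a list with other genes, in either arm against Control. Of 134 measured members of an IL2-STAT5 signalling list, which shares 12 genes with the STAT5 targets, 46 rose and 29 fell in WT (49 and 32 adjusted over the list alone) and 46 rose and 31 fell in IDRmut (50 and 32 adjusted over the list alone), with camera adjusted p of 0.31 and 0.88 and fry adjusted p of 0.013 and 0.36. Among 29 JAK-STAT components 6 rose and 4 fell in WT (6 and 4 adjusted over the list alone) and 7 rose and 4 fell in IDRmut (10 and 8 adjusted over the list alone). Camera adjusted p were 0.18 and 0.15, and fry gave both arms a direction upward, at adjusted p of 0.0033 and 0.0034. Between WT and IDRmut the IL2-STAT5 list had 37 members higher and 20 lower in WT (43 and 25 adjusted over the list alone). Its camera adjusted p was 0.23, and fry gave an upward direction at adjusted p 0.022. Of the JAK-STAT components 4 were higher and 5 lower (4 and 5 adjusted over the list alone), with camera and fry adjusted p of 0.99 and 0.72. Partners and substrates of ACK1 rose in 10 of 32 cases and fell in 8 in WT against Control (11 and 8 adjusted over the list alone), and rose in 5 and fell in 10 in IDRmut (5 and 11 adjusted over the list alone). Camera adjusted p were 0.35 and 0.43, while fry gave an upward direction in WT (adjusted p 0.018) and a downward one in IDRmut (adjusted p 0.040). They were higher in 13 and lower in 6 in WT than in IDRmut (13 and 6 adjusted over the list alone). That difference had a camera adjusted p of 0.014, against adjusted p = 0.17 with an estimated correlation.

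The changes from Control in WT and in IDRmut overlapped. Of the genes called against Control, 1526 rose in both arms, 1556 fell in both and 209 went opposite ways, so that 3082 calls, 53.1% of those in WT, were shared in direction. Lists drawn independently would share 451 higher and 465 lower genes, a value that leaves out the shared Control libraries. Simulations without effects that keep those libraries gave a mean overlap of 0.1 genes and at most 1, but called at most 5 genes each between WT and Control and so give no measure for lists of this size. Across genes, which are not independent replicates, the fold changes correlated at r = 0.859, against 0.537 in the simulations, with a covariance of 0.464 against 0.0247, a difference of 0.440. The simulated covariance is what sharing Control libraries gives from the spread between replicates alone. A difference of the Control culture as a whole from both ACK1 cultures is not in the simulations, and part of the excess may come from it. A split of the 2 Control libraries leaves 1 for each arm and was not made for this overlap. The overlap was 1865 with DESeq2 and 1983 without Control replicate 1. Among shared genes, 382 of those that rose were higher still in WT than in IDRmut and 175 were lower, and of those that fell 242 were lower still and 229 higher.

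**Figure D3:**
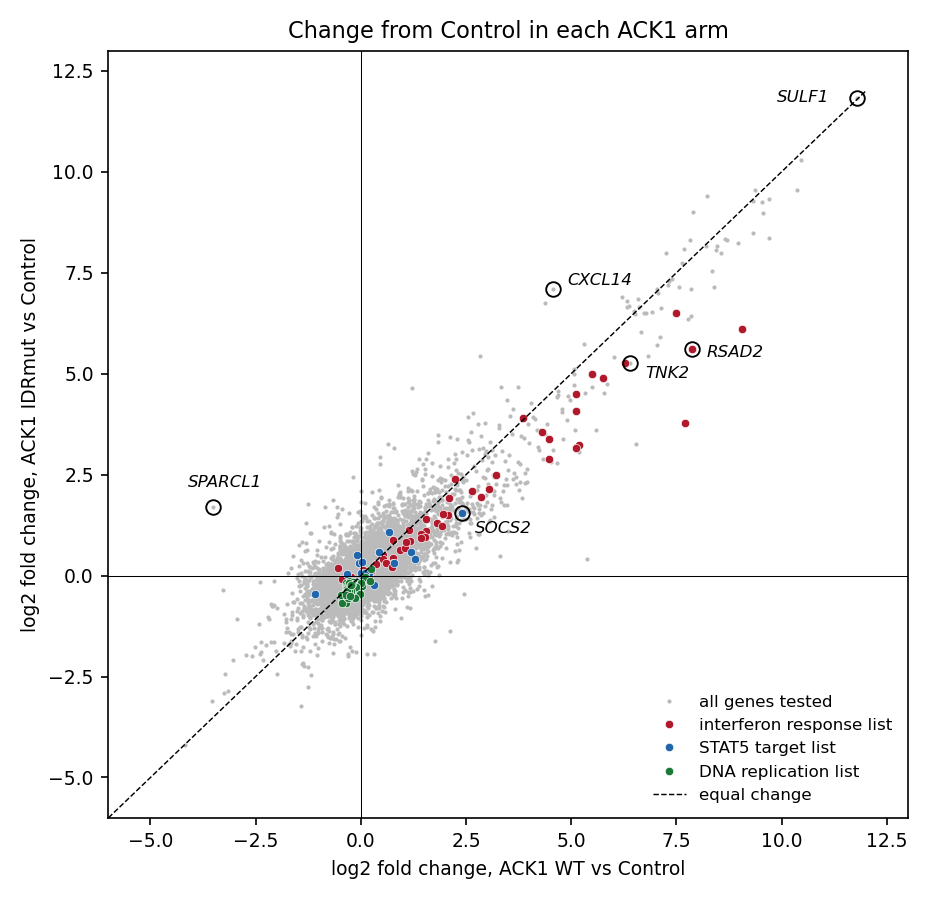
Log2 fold change of each of 16591 genes in WT (horizontal) and IDRmut (vertical) against Control, with the interferon, STAT5 target and DNA replication lists in colour, named genes ringed and a dashed line of equal change. Interferon genes, with a median difference of 0.45 between WT and IDRmut, lie mostly to the right of the line; fitted values of genes without Control counts, such as SULF1, depend on the prior count and are not bounds.

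Most single markers of other cell types were low, while CDH5, COL1A2 and CAPS were abundant. Endothelial markers summed to 220 and 226 CPM in Control, 51.2 and 53.2 CPM in WT and 103 and 99.6 CPM in IDRmut. CDH5 made up most of these sums, with 39.2 and 39.7 CPM in WT, where KDR had 5.88 and 6.55 CPM. Fibroblast markers summed to 884 and 908 CPM in Control, 707 and 718 CPM in WT and 987 and 927 CPM in IDRmut, with COL1A2 the most abundant, and 4 of 8 were lower in WT than in IDRmut and none higher (4 and 0 adjusted over the list alone). That list, whose genes the epithelial-mesenchymal transition can also raise, had a camera adjusted p of 0.0013 between the arms, with adjusted p = 0.15 with an estimated correlation. Airway markers summed to 333 and 345 CPM in Control, 432 and 448 CPM in WT and 389 and 324 CPM in IDRmut, mostly CAPS (0.42 ± 0.07 in WT against Control; 19.5% of its exon bases overlapped). Leukocyte markers summed to at most 4.75 CPM, neuroendocrine markers to at most 30.2 CPM and alveolar markers to at most 0.819 CPM in any library. Single markers of low level were called higher in both arms against Control, among them TEK, the neural adhesion gene NCAM1 (log2 fold changes of 4.13 ± 0.31 in WT and 3.88 ± 0.33 in IDRmut) and the collagen gene COL1A1 (1.72 ± 0.32 and 1.84 ± 0.33). The endothelial receptor gene TEK stood at 1.07 ± 0.0074 CPM in Control, 5.10 ± 0.56 CPM in WT and 2.65 ± 0.14 CPM in IDRmut (SD, n = 2). COL6A3 was called in IDRmut at 1.22 ± 0.40, a call lost with DESeq2 (adjusted p 0.16), without either Control library (edgeR adjusted p 0.12 and 0.13) and without ACK1 IDRmut replicate 1 (0.085).

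Genes that differed in WT from both Control and IDRmut in the same direction numbered 2207, with 1183 higher and 1024 lower. These were 40.9% of the genes higher and 35.1% of the genes lower in WT than in Control. Independent lists would share 409 higher and 360 lower genes, which leaves out that both comparisons use the same WT libraries. Simulations without effects gave a mean of 0.45 and at most 2, again from at most 5 calls each between WT and Control. RSAD2, IFIT2, CXCL8 and SOCS2 were among the higher genes, and SPARCL1 among the lower. The set held 1192 genes with DESeq2 and 1305 without ACK1 WT replicate 2. In 1723 of the 4396 genes that differed between the arms, the IDRmut level was called outside the range from Control to WT, above both in 798 genes and below both in 925. Both calls use the same IDRmut libraries, and no simulated value was computed for this count.

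Fold changes against Control were also shared between neighbouring genes on chromosomes 1 and 7. The 187 expressed genes on chromosome 1 from 193012250 to 248859144 had a median log2 fold change of 0.15 in WT and 0.13 in IDRmut, with 74.9% and 72.2% of genes above 0. The 156 genes on chromosome 7 from 103074881 to 158956747 had medians of -0.21 and -0.18, with 85.9% and 85.3% below 0, while the remaining 9677 genes had a median of -0.03 in both arms. Between WT and IDRmut these segments differed by -0.01 and -0.04. Over 245 windows of neighbouring genes the SD of window medians was 0.0621 in WT and 0.0566 in IDRmut, against at most 0.0394 and 0.0390 in 200 shuffles. It was 0.0362 between WT and IDRmut, against at most 0.0350. Replicates of one group also differed by window, with 0.0233 in Control against at most 0.0170 and 0.0554 in IDRmut against at most 0.0245. After a trend with GC content and transcript length was removed, these fell to 0.0152 and 0.0137, within their shuffles, while WT and IDRmut against Control stood at 0.0615 and 0.0567. Both segments were picked after the values were seen; without their genes edgeR called 5535 genes in WT and 5000 in IDRmut against Control.

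**Figure D4:**
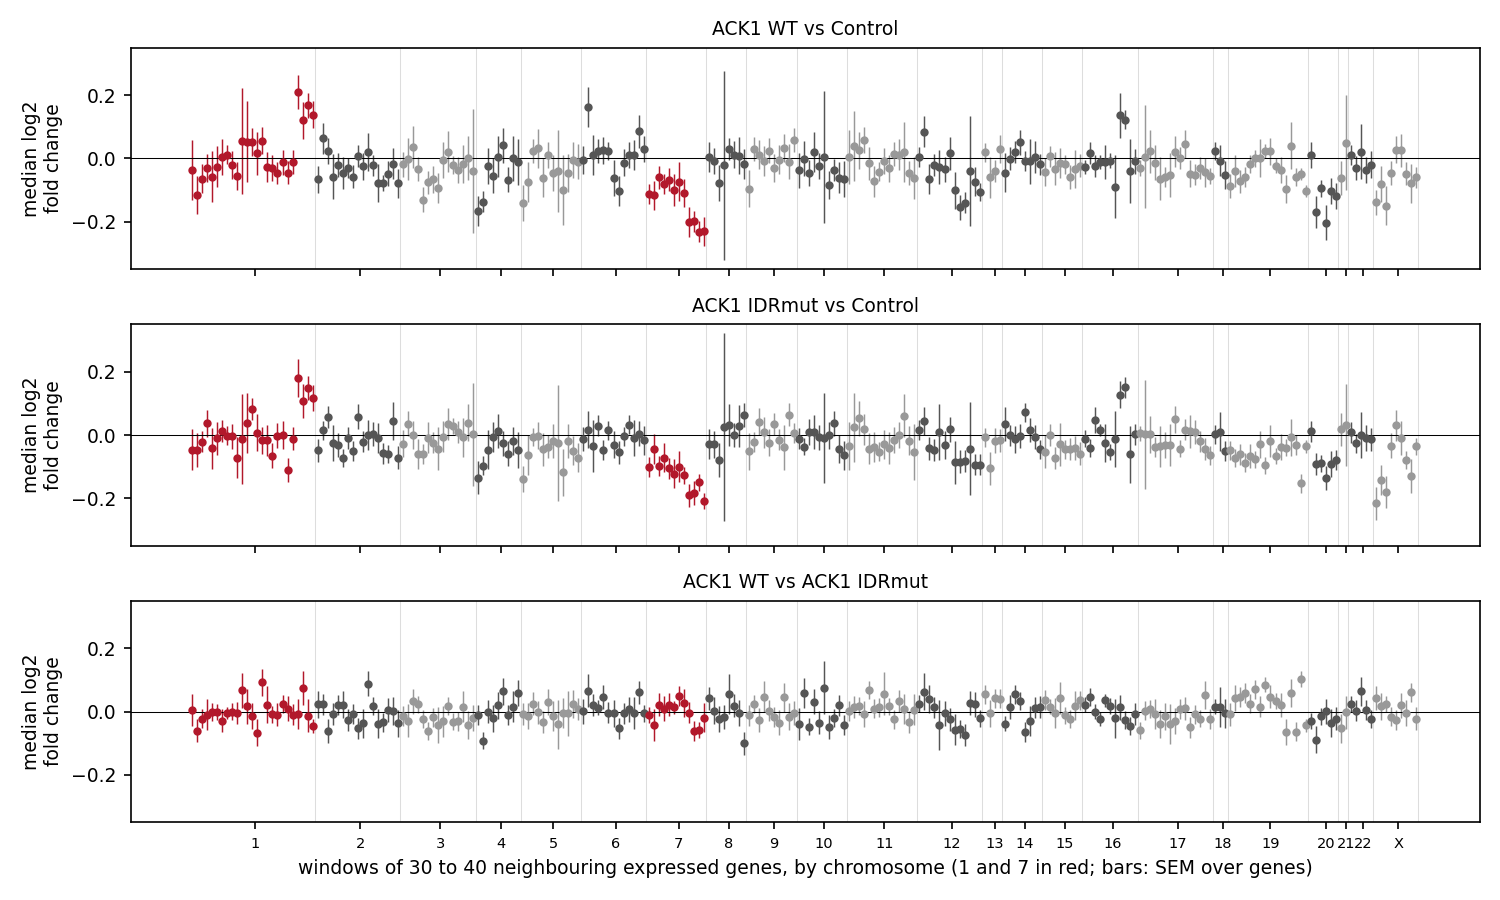
Median log2 fold change of windows of 30 to 40 neighbouring expressed genes along the chromosomes in the 3 comparisons, with the SEM over genes as bars and chromosomes 1 and 7 in red. The end of chromosome 1 lies above 0 and the end of chromosome 7 below 0 in both ACK1 arms against Control, and neither stands out between WT and IDRmut.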

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

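The correction for GC content and transcript length and the counts without the shifted segments were chosen after the data were seen; the others were fixed beforehand. Where no reason is given for a change, the cause was not tested. In the order WT against Control, IDRmut against Control, WT against IDRmut, genes distinct in WT from both, and genes shared by both arms, the counts were 5807, 5237, 4396, 2207 and 3082. DESeq2 gave 3649, 3290, 2435, 1192 and 1865. A log2 fold change of at least 1 left 1056, 862, 424, 214 and 545, by construction fewer. An adjusted p under 0.01 left 3478, 2757, 1348 and 2005 for the last 4 counts. Leaving out one library, with the lone library of its group assumed to vary like the other groups, gave ranges of 3974 to 7028, 3451 to 5522, 2590 to 4761, 1305 to 2503 and 1983 to 3343. The lowest values for IDRmut against Control and for the shared genes came without Control replicate 1, and those for WT against IDRmut and for genes distinct in WT came without ACK1 WT replicate 2, the deepest library. Replicate numbers shared only a number (correlations of replicate differences across genes of -0.021, -0.024 and -0.029), and a replicate block gave 5440, 4836, 3966, 1977 and 2826. RLE and upper-quartile scaling, limma-voom, the other filters and fits of only the groups compared stayed within a factor of 1.5 of these counts. The correction for GC content and length gave 7076, 6223, 5722, 3085 and 3845, and leaving out the shifted segments gave 5535, 5000, 4263, 2132 and 2911.

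Camera with an estimated correlation, which had only 3 degrees of freedom, called 0, 2 and 0 lists in the 3 comparisons. Directional fry, which does not compare a list with other genes, called 28, 22 and 28. TNK2 kept its direction and its call in every alternative run, from 6.37 to 6.43, 5.11 to 5.38 and 1.02 to 1.29 without single libraries. All 420 fold changes of named genes were run, whether called or not. Of these 368 were called, and none of the called ones changed sign. Calls were lost 45 times over all alternatives, 12 of them with DESeq2, and in 31 cases an uncalled value passed the threshold with its sign kept. Signs changed only for values that were not called in the main fit. Without single libraries these were, against Control in WT, CCND1 (-0.0032 to 0.027), CCND3 (-0.0046 to 0.038), BCL2L1 (-0.044 to 0.055) and SCGB3A2 (-0.27 to 0.0086). In IDRmut they were PIM1 (-0.10 to 0.0056), PIM2 (-0.011 to 0.12), BCL6 (-0.012 to 0.098), SOCS1 (-0.0052 to 0.94), SOCS3 (-0.085 to 0.18), SYP (-0.33 to 0.17) and CAPS (-0.15 to 0.17). CAPS was called in opposite directions without ACK1 IDRmut replicate 1 (edgeR adjusted p 0.0012) and without replicate 2 (3.3e-04). Between WT and IDRmut they were SOCS3 (-0.076 to 0.19) and DUSP5 (-0.063 to 0.078). With the correction for GC content and length they were PIM1 (-0.0058), CCND1 (-0.016), CCND3 (-0.036) and BCL2L1 (-0.041) in WT against Control and DUSP5 (-0.025) between the arms. CISH and SOCS1 had few counts in every library.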

Other observations

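The tests on patterns were chosen after the results were seen, except that of GC content and transcript length on neighbouring genes. The gene lists were fixed before, and a pair of counts in parentheses is adjusted over the list alone. In WT against Control, p53 targets rose in 13 of 26 cases and fell in 3 (14 and 4 adjusted over the list alone), with CDKN1A at 1.20 and the cytokine GDF15 at 2.04, and YAP-TEAD targets rose in 13 of 24 and fell in 3 (13 and 4). Immediate early genes rose in 13 of 26 and fell in 4 (14 and 4), with ATF3 at 2.61, and immune checkpoint genes rose in 9 of 15 and fell in none (9 and 1), with CD274, the ligand PD-L1, at 1.15. IDO1 had 2 counts in Control and a WT to Control ratio of 46.0 (95% counting interval 12.5 to 383). Integrated stress genes rose in 17 of 39 and fell in 11 (17 and 12), and heat shock chaperones rose in 7 of 26 and fell in 2 (7 and 2), with the small chaperone CRYAB at 3.39 (38.7% of its exon bases overlap other genes). Glycolysis and hypoxia genes fell in 18 of 36 and rose in 3 (18 and 3), and mitochondrially encoded transcripts fell in 7 of 15 and rose in 2 (7 and 2). Camera adjusted p for these lists were 4.6e-04, 4.6e-04, 0.0036, 0.0017, 0.011, 0.011, 0.0046 and 0.018 in that order, and with an estimated correlation adjusted p = 0.15, 0.23, 0.39, 0.15, 0.15, 0.23, 0.23 and 0.61; the last call was lost without Control replicate 2 (camera adjusted p 0.13) and without ACK1 WT replicate 2 (0.069). In IDRmut against Control the epithelial-mesenchymal transition (17 higher and 7 lower of 32; 19 and 7 over the list alone), FOXO target (5 and 2 of 21; 6 and 3), integrated stress (16 and 5 of 39; 16 and 6) and mitochondrially encoded lists (7 and 1 of 15; 8 and 1) were higher. Camera gave them adjusted p of 5.2e-05, 0.0065, 0.015 and 0.048, and with an estimated correlation adjusted p = 0.14, 0.18, 0.18 and 0.74. The last of these was lost without Control replicate 1 (camera adjusted p 0.44), without ACK1 IDRmut replicate 2 (0.21) and with the correction for GC content and length (0.13).

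Between WT and IDRmut, immediate early, p53, inflammatory, checkpoint, histone, epithelial-mesenchymal, endocytosis, BCL2 family and cholesterol synthesis lists were higher in WT, and ribosome biogenesis genes were lower. Members higher and lower were 10 and 2 of 26, 9 and 1 of 26, 10 and 4 of 20, 9 and 2 of 15, 8 and 0 of 13, 13 and 9 of 32, 16 and 3 of 40, 7 and 1 of 16, 10 and 2 of 26, and 2 and 17 of 36. Adjusted over the list alone they were 10 and 2, 10 and 2, 12 and 4, 9 and 2, 10 and 0, 15 and 9, 18 and 3, 8 and 1, 11 and 2, and 2 and 18. Camera adjusted p were 9.2e-04, 0.0047, 0.0053, 0.0053, 0.0053, 0.014, 0.014, 0.037, 0.039 and 0.0013, and with an estimated correlation adjusted p = 0.30, 0.17, 0.16, 0.16, 0.16, 0.23, 0.16, 0.21, 0.31 and 0.26. The BCL2 family and cholesterol calls were lost with the correction for GC content and length (camera adjusted p 0.061 and 0.093) and without ACK1 IDRmut replicate 2 (0.071 and 0.086), the former also without ACK1 IDRmut replicate 1 (0.059) and the latter without ACK1 WT replicate 2 (0.081). The lists of fatty acid metabolism (7 higher and 3 lower of 20 in WT against Control; 7 and 4 over the list alone), NRF2 targets (9 and 8 of 28; 9 and 8), Wnt and Notch targets (7 and 4 of 17; 8 and 4), keratinocyte differentiation (4 and 0 of 7; 4 and 0) and the nuclear-encoded respiratory chain (3 and 16 of 50; 3 and 18) passed in no comparison, with camera adjusted p in WT against Control of 0.82, 0.63, 0.47, 0.19 and 0.079. The median, mean and test differed in sign in 11 of 102 tests of a list in a comparison, none of them called, such as TGF-beta targets in IDRmut against Control (median -0.09, mean 0.08). Genes of interferons themselves, chosen after their values were seen, had few counts: IFNB1 had 0 and 0 in Control, 5 and 5 in WT and 1 and 2 in IDRmut, and the interferon-induced chemokine gene CXCL10 had 0 and 0, 61 and 101, and 8 and 8.

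Neighbouring genes on chromosomes 1 and 7 shifted together in both ACK1 arms against Control. A trend with GC content and transcript length was argued against as the whole cause, since the SD of window medians in WT against Control was 0.0615 after its removal, above the highest of 200 shuffles at 0.0396, while the same correction took the difference between the IDRmut replicates from 0.0554 to 0.0137. Of 11 windows chosen for a shift in Control 1 and WT 1, 3 were on chromosome 1, 4 on chromosome 7 and 1 each on chromosomes 6, 12, 16 and 20. In Control 2 and IDRmut 2, 73.7% of their genes lay on the same side (55% in that on chromosome 12). These windows were not corrected for GC content and length. A difference in copy number or clonal makeup between the Control culture and both ACK1 cultures predicts this, and so does a regional response to ACK1. Changes of single genes shared by both arms could add to it. Such changes, placed without regard to position, are argued against as the whole cause of the window shifts. The SD of window medians stood above the highest of 200 shuffles of gene positions in both arms, also after the correction (0.0567 against 0.0383 in IDRmut). Over all genes tested, 72.7% had fold changes of the same sign in both arms against the shared Control libraries, where simulations without effects gave 67.6%. The 73.7% instead compares each gene with its window, in pairs that share no library, so the 72.7% is no baseline for it. No shuffled value of the 73.7% was computed. A difference in copy number or clonal makeup and a regional response predict the same share. It cannot decide between them, and both stay open, since no library separates them.

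After thinning to equal depth, 36 genes were low in Control and present in both ACK1 arms and 1 gene showed the reverse, so depth was argued against. Of these, 34 were outside the interferon list, such as SULF1, FLRT2 and ADGRL4 (the last 2 named after their values were seen). Among 51 such genes chosen from Control and WT alone, with no condition on IDRmut, the median log2 ratio of WT over IDRmut was 0.44 (quartiles 0.16 and 0.95) against 1.15 for TNK2, which argues against expression in proportion to the ACK1 transcript for the set, though not for the 11 genes at or above that ratio. Of the 6 marker sums 0 were higher in all 4 ACK1 libraries than in both Control libraries, while of the 60 single markers 10 were, at up to 5.50 CPM, among them NCAM1, TEK, COL1A1 and COL6A3, and 3 were lower in all 4. RNA of other cell types cannot be told apart from expression in H2170 by these values, because high baselines of COL1A2, CDH5 and CAPS would hide a small share in the sums. A clonal difference between the cultures, or an all-or-none response to either form of ACK1, may underlie these genes, and neither was tested.

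WT and IDRmut differed both in the ACK1 sequence and in the TNK2 level, so a graded response to the ACK1 transcript is the main alternative to an effect of the IDRmut change. For 1723 of the 4396 genes that differed between the arms (39.2%), the IDRmut level lay outside the range from Control to WT. Both calls behind this count use the same IDRmut libraries, so an error or preparation difference in IDRmut moves both at once. The IDRmut replicates also differed most, with a chi-square per gene of 3.72. No value without effects was simulated for this count. Such differences aside, it argues against a response of these genes that only rises or only falls with the transcript level. A response that turns at a middle level could give the same pattern and stays open. A graded response together with a difference of the Control culture from both ACK1 cultures could as well. The count was 920 with DESeq2, 990 at an adjusted p under 0.01 by edgeR, and 116 of 424 with a log2 fold change of at least 1. Another 1998 genes (45.5%) were called in WT against Control in the same direction, with IDRmut not called outside the range from Control to WT. For these the sequence change and the lower level cannot be told apart, since no library has WT at the IDRmut level. The interferon list, with medians of 1.69 and 1.26, lies in this range. The remaining genes that differed between the arms fell in neither part and were not weighed. A difference between independently made cultures stays open for all 4396 genes, as 1 culture or several per group is not stated.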
